A study of Mus musculus with 5 samples.

How the data were processed

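Genomic DNA of mouse iPSC clones was analysed by RRBS. Per the labels' protocols, the DNA was purified with a column kit and the libraries followed a published enhanced RRBS protocol. The authors deposited 1 table per library with a coverage count for each CpG cytosine and the percent of its reads that read C (methylated) or T (unmethylated). The coverage was deposited as raw counts, not normalized, and the percent values are per cytosine. Per the submitters' processing notes the genome build was mm10 and CASAVA 1.8.2 was used, with no role stated. The aligner, the methylation caller and their filters are not given in the sources used here, nor is any sequencing batch or date, so that genotype and a library batch cannot be told apart.

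Methylated and unmethylated reads were recovered as coverage times percent and rounded. At least 99.9996% of products lay within 0.05 of a whole number in each library. Reads of other bases, present at 0.0818% to 0.219% of cytosines, were left out of the level. The 2 strands of a CpG were merged. The deposited tables listed 6693672 and 11454322 cytosines in AICDA KO replicates 2 and 3, at a median coverage of 3 and 2. They listed 5127118, 5722147 and 5676912 in WT replicates 1, 2 and 3, at a median coverage of 5, 4 and 4. CpGs in any library numbered 13633948. CpGs covered at least 10 times in every library numbered 1011693, of which 991900 were autosomal. The 10 most covered cytosines held 4.28% to 7.70% of the summed coverage. Methylation of the mitochondrial genome, an upper bound on unconverted cytosines there, was 0.174% to 0.230%. RRBS reads have no molecular identifiers, so that coverage counts reads and not molecules. A level at 10 reads moves by 10 points per read, and regions summed at least 3 CpGs.

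Samples were grouped by the genotype in the labels, with replicate numbers from the titles. The labels do not say whether replicates came from separate animals or reprogramming experiments. The level of a class of CpG is the unweighted mean over its CpGs. The level of a tile or gene end is methylated over all reads summed over its CpGs, per library, and group means weight libraries equally. Genes came from a RefSeq table of assembly GRCm38.p6, the assembly of mm10, which gives gene spans without strand or exons. 34623 of its 49997 genes were used, and all but 2 of the 501 entries of the gene lists matched. Without strand, the promoter was taken as the gene end with more CpGs (1000 bp outside to 500 bp inside the gene), so that some of these windows lie at the 3' end. Exons, introns, untranslated regions and CpG islands were not analysed here, since no genome sequence or exon table was used. CpG density, the number of CpGs within 250 bp of a CpG, itself included, counted over all libraries, took the place of CpG islands. A tile outside genes was named by its nearest named coding gene. In lowered tiles near Aicda, a CpG counted as keeping methylated reads when the lower 95% binomial bound of its methylated share over the AICDA KO reads lay above 2%.

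Levels were compared by exact permutation tests over all 10 splits of the libraries, 2-sided, with Benjamini-Hochberg adjustment over classes. Tiles of 1000 bp and gene ends with at least 3 covered CpGs were tested with the edgeR quasi-likelihood test on methylated and unmethylated reads with a coefficient per library. Single CpGs were tested with a quasi-binomial logistic test whose dispersion was moderated by limma's squeezeVar with a floor of 1. A call needed a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 10 points. Regions and CpGs with only methylated or only unmethylated reads in all libraries got no p. camera (preset correlation 0.01) and fry ran on log2((methylated + 2)/(unmethylated + 2)) of gene ends. The 10 gene lists were pluripotency, primed state, FGF and ERK pathway, imprinted, germline, fibroblast, epithelial, DNA methylation, developmental regulators and B cell. Groups, tests, thresholds, lists and the rule for named genes were fixed before the data were examined. Fits restricted to regions with a mean level of 20 to 80% over all 5 libraries, the gene-end definition and the density classes were chosen after the data were seen.

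The rule for named genes took Aicda first. It then took the 10 called gene ends with the largest rise and the 10 with the largest fall in which both AICDA KO libraries lay on 1 side of all WT libraries, leaving out predicted genes and pseudogenes and counting shared windows once. It also took every called member of a list, 16 genes fixed by name (13 of them measured), and the 5 tiles with the largest rise and the 5 with the largest fall. Where fewer than 5 passed, the 5 with the smallest p were given as values. The rule was applied to the fit over all regions, where nothing was called, and again to the intermediate fit.

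The tests were checked on simulated data with reads drawn at the real coverage. The between-library spread was that of the WT libraries at intermediate levels, used for every region. In these data 200 regions were changed by 15 or 30 points and the rest left unchanged. Of unchanged regions 4.41% of intermediate gene ends and 4.88% of intermediate tiles had an edgeR p under 0.05. edgeR's fits over all 16055 gene ends and all 102353 tiles recovered 0% of the changed regions, and the quasi-binomial test and limma recovered 0% too. At CpGs the quasi-binomial test and limma recovered 0%. When all intermediate regions were raised by 14 points, edgeR at intermediate levels called 38.3% of gene ends and 30.6% of tiles.

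The alternatives were coverage minimums of 5 and 20, a coverage maximum at the 99.9th percentile, separate strands, inclusion of X and Y, thinning to equal coverage, leaving out each library, a replicate block, other tests, other difference thresholds, at least 5 CpGs per region, 500 bp tiles, a gene window of 500 bp either side, centring, an estimated correlation in camera and pooled reads. Added later were the CpG-poorer gene end, the whole gene span and centring over intermediate regions. Tools were R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.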

Results

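CpG methylation was measured by reduced representation bisulphite sequencing (RRBS), which reads the CpG-rich share of the genome around restriction sites and scores each read of a cytosine as methylated or unmethylated. The samples were mouse induced pluripotent stem cell (iPSC) clones made from fibroblasts with the OSKM reprogramming factors, grown in serum with leukaemia inhibitory factor (LIF) and taken at passage 4. 3 libraries came from wild-type (WT) cells (replicates 1, 2 and 3) and 2 from AICDA knockout (KO) cells (replicates 2 and 3). Aicda encodes activation-induced cytidine deaminase, which deaminates cytosine in the antibody genes of B cells. The design asks how CpG methylation differs between iPSCs made with and without this enzyme. The summed coverage of cytosines was 58830901 and 62101658 in AICDA KO replicates 2 and 3, and 75676672, 76077857 and 71601676 in WT replicates 1, 2 and 3. The comparisons used 991900 autosomal CpGs covered at least 10 times in every library, at a median coverage of 28 in both AICDA KO libraries and of 38, 41 and 39 in the WT libraries. Replicates of 1 genotype differed by more than the counting error of reads taken as independent, to which PCR copies add, with a mean chi-square per 1 kb tile of 3.53 between the AICDA KO libraries and of 4.60 to 5.57 between WT pairs. With 2 against 3 libraries the smallest 2-sided p an exact permutation test can give is 0.1. The p-values of edgeR, limma, the quasi-binomial test, fry and the exact permutation tests rest on the spread between these clones.

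Coverage within the Aicda gene separated the libraries by genotype label. Within the gene (mm10, chromosome 6, 122553809 to 122564180), a segment of 8 CpGs at 122561052 to 122561158 held 140, 222 and 239 reads in WT replicates 1, 2 and 3 and 11 and 8 reads in AICDA KO replicates 2 and 3. No CpG of the segment had more than 3 reads in an AICDA KO library, against up to 57 in WT. CpGs elsewhere within 20 Mb of Aicda lacked reads in AICDA KO too (below), so that this loss may not mark the knockout itself. Coverage was kept at the other covered segments of Aicda: 37 and 37 reads in AICDA KO against 65, 70 and 66 in WT at 122554079 to 122554152, and 314 and 309 against 136, 303 and 481 at 122563403 to 122563452. At the last of these segments 4 CpGs were methylated at 8.67% ± 0.356 (SD, n = 2) in AICDA KO and 28.2% ± 4.27 (SD, n = 3) in WT.

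Methylation was higher in both AICDA KO libraries than in all WT libraries in most classes of CpG, and by least where levels were low. The mean level over autosomal CpGs was 32.3% ± 0.0767 (SD, n = 2) in AICDA KO and 25.9% ± 0.357 (SD, n = 3) in WT, a difference of 6.40 percentage points (exact permutation test, p = 0.1). Intergenic CpGs were at 59.2% ± 0.0506 (SD, n = 2) in AICDA KO against 47.5% ± 0.631 (SD, n = 3) in WT, and gene bodies at 39.96% ± 0.0482 against 31.9% ± 0.420. CpG-richer gene ends, the end of each gene that holds more CpGs and that stands here for the promoter, differed by 0.712 points, at 4.40% ± 0.158 against 3.68% ± 0.103. CpGs of intermediate methylation (20 to 80% over all libraries) carried the widest difference by level, 65.3% ± 0.00352 (SD, n = 2) in AICDA KO against 51.1% ± 0.763 (SD, n = 3) in WT, or 14.2 points. CpGs over 80% differed by 8.92 points and those under 20% by 0.304 points. In 9 of 10 classes of CpG both AICDA KO libraries lay above all WT libraries. Each of these 9 had an exact permutation p of 0.1, adjusted to 0.111 by Benjamini-Hochberg over the 10 classes. The exception was the class with over 25 CpGs within 250 bp, at 1.32% ± 0.193 against 1.25% ± 0.0815, where the libraries overlapped (exact permutation test, p = 0.6).

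**Figure D1:**
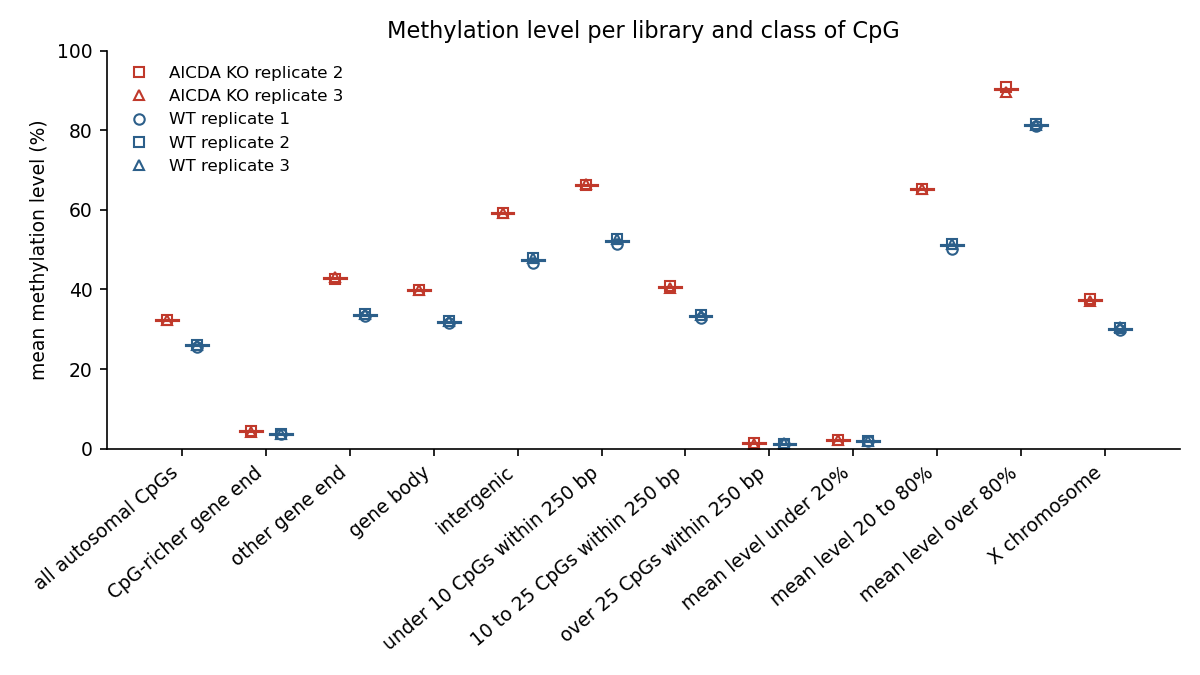
Mean methylation level in percent (vertical axis) of each library by class of CpG (horizontal axis); red symbols are AICDA KO, blue symbols WT, symbol shape gives the replicate number and bars the group means. The AICDA KO mean is 32.3% over all autosomal CpGs against 25.9% in WT, and the libraries overlap at over 25 CpGs within 250 bp.

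The distribution of CpG levels differed in its upper part. In AICDA KO replicates 2 and 3, 8.86% and 9.60% of CpGs lay between 80 and 90%, against 3.58%, 3.87% and 3.81% in WT replicates 1, 2 and 3. CpGs under 10% made up 49.8% and 50.01% in AICDA KO and 51.3%, 51.0% and 50.9% in WT. Intermediate CpGs were higher in both AICDA KO libraries than in all WT libraries on each of the 19 autosomes, by 13.4 points on chromosome 19, the smallest difference, to 14.6 on chromosome 16, the largest.

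**Figure D2:**
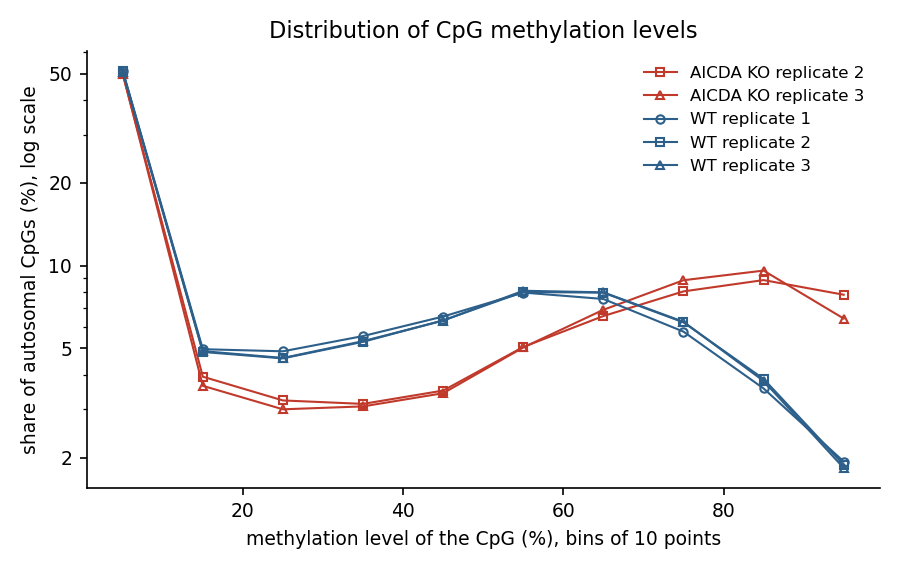
Share of autosomal CpGs in percent (vertical axis, log scale) by methylation level in bins of 10 points (horizontal axis), 1 line per library. Between 80 and 90% the AICDA KO lines lie at 8.86% and 9.60% and the WT lines at 3.58% to 3.87%.

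The difference was widest at CpGs with few other CpGs nearby. Only CpGs read in any library were counted, so that a low count can also mean unread CpGs. Among CpGs of intermediate level, those with fewer than 5 CpGs within 250 bp stood at 71.2% ± 0.416 (SD, n = 2) in AICDA KO and 53.5% ± 0.938 (SD, n = 3) in WT, a difference of 17.7 points. The difference was 12.7 points at 10 to 14 CpGs, 8.38 points at 20 to 24 and 6.35 points at 25 to 29 (43.7% ± 2.96 against 37.4% ± 0.456). It was 10.4 points at 40 or more CpGs, a class of 586 CpGs. In each class both AICDA KO libraries lay above all WT libraries (exact permutation test, p = 0.1). AICDA KO replicate 3 lay below replicate 2 at every density from 10 CpGs up, most at 30 to 39 CpGs, where the levels were 34.6% and 41.1% against 31.1%, 33.3% and 33.2% in WT.

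**Figure D3:**
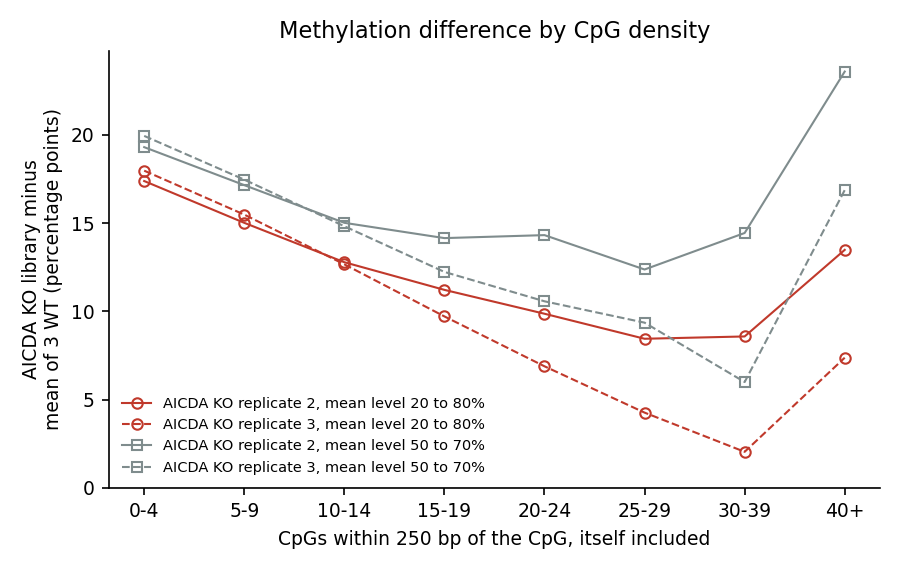
Methylation of each AICDA KO library minus the mean of the 3 WT libraries in percentage points (vertical axis) by the number of CpGs within 250 bp (horizontal axis), for CpGs with a mean level of 20 to 80% (red circles) and of 50 to 70% (grey squares); solid lines are replicate 2 and dashed lines replicate 3. The mean difference at 20 to 80% falls from 17.7 points at fewer than 5 CpGs to 6.35 points at 25 to 29.

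On the X chromosome methylation was higher in AICDA KO as well. Its 19451 CpGs were at 37.4% ± 0.293 (SD, n = 2) in AICDA KO and 30.2% ± 0.315 (SD, n = 3) in WT, a difference of 7.22 points (exact permutation test, p = 0.1). X chromosome CpGs with over 25 CpGs within 250 bp were at 2.53% ± 0.409 in AICDA KO and 2.08% ± 0.0192 in WT. The median coverage of X relative to autosomal CpGs was 1.07 in AICDA KO replicate 2, 0.75 in replicate 3, and 1, 1.02 and 1.03 in the WT libraries. Cytosines of the Y chromosome made up 0.112 to 0.175 per 1000 autosomal cytosines in the 5 libraries.

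Most regions of intermediate methylation were higher in AICDA KO. In 1 kb tiles, both AICDA KO libraries lay above all WT libraries in 48.9% of 102353 tiles and below them in 2.48%, where chance gives 10% each. edgeR's quasi-likelihood test over all tiles called 0 of 101318 (lowest adjusted p = 0.0758). 31884 tiles had an unadjusted p under 0.05, 31023 of them higher in AICDA KO. The moderated quasi-binomial test called 18115 tiles, limma 0 and a binomial test without overdispersion 48101. In simulated libraries with the same spread, edgeR over all tiles recovered 0% of changes of 15 or of 30 points. A fit restricted to the 67446 tiles of intermediate level, added after the data were seen, recovered 1% and 34% of such changes. That fit called 24077 tiles (edgeR, adjusted p under 0.05 and at least 10 points), 24030 higher and 47 lower in AICDA KO, with a median difference of 13.7 points over the tiles tested. The quasi-binomial test called 21638 of the intermediate tiles and limma 16869, with 14698 shared by the 3 tools. Without AICDA KO replicate 2 edgeR called 6560, and without replicate 3 10744. With the median log ratio of each library subtracted, limma called 0 intermediate tiles (lowest adjusted p = 0.123; 6312 at an unadjusted p under 0.05, 2491 above and 3821 below the shared shift).

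The tiles with the smallest p for a rise in the all-tile fit included chromosome 18, 69563001 to 69564000 in Tcf4, a transcription factor gene. It was at 90.7% ± 0.533 (SD, n = 2) in AICDA KO and 58.9% ± 1.30 (SD, n = 3) in WT (edgeR at intermediate levels, adjusted p = 0.000729). Others lay 43429 bp from Fbn2 on chromosome 18 (96.2% ± 0.266 against 65.5% ± 2.16), near Ccl1 on chromosome 11 (88.7% ± 0.958 against 54.8% ± 2.85) and near Rerg on chromosome 6 (87.5% ± 2.59 against 47.8% ± 5.21). A tile shared by Atp5pb and Wdr77 on chromosome 3, 105959001 to 105960000, was at 8.03% ± 1.10 in AICDA KO and 0.0651% ± 0.0689 in WT (edgeR over all tiles, adjusted p = 0.0758). Of the intermediate tiles called, the largest rises were in Vtcn1 (chromosome 3, 100886001 to 100887000; 84.4% ± 0.935 against 30.2% ± 29.0), in Traf2, in Stc2, near Ddhd1 and near Cldn10. The Vtcn1 tile rested on 37 reads in its lowest library, and WT replicate 3 stood at 62.5%.

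The called tiles that fell in AICDA KO were few, and 10 of the 47 lay within 20 Mb of Aicda on chromosome 6. That window held 1048 of the 67446 intermediate tiles (Fisher's exact test, odds ratio 17.3, p = 2.42e-09). The test counts tiles as independent, which tiles linked to 1 gene need not be. The largest fall was at 134807001 to 134808000, in Dusp16, a phosphatase gene, at 10.2% ± 1.23 (SD, n = 2) in AICDA KO and 52.9% ± 8.31 (SD, n = 3) in WT (edgeR at intermediate levels, adjusted p = 0.00175). The Aicda tile at 122563001 to 122564000 (8.67% ± 0.356 against 28.2% ± 4.27) was called as well. Outside this window the largest falls were on chromosome 5 in C330024D21Rik and Cnot6l, on chromosome 13 in Cdhr2 (26.3% ± 1.19 against 62.2% ± 17.5) and on chromosome 9 in Zic4 (8.74% ± 2.26 against 41.5% ± 15.4). The same window of chromosome 6 was covered unequally. 197 autosomal CpGs had at least 20 reads in every WT library and none in both AICDA KO libraries, and 188 of them lay within 20 Mb of Aicda. The tile near Rerg and the gene ends of Tpi1 and Magohb named below lie in it.

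**Figure D4:**
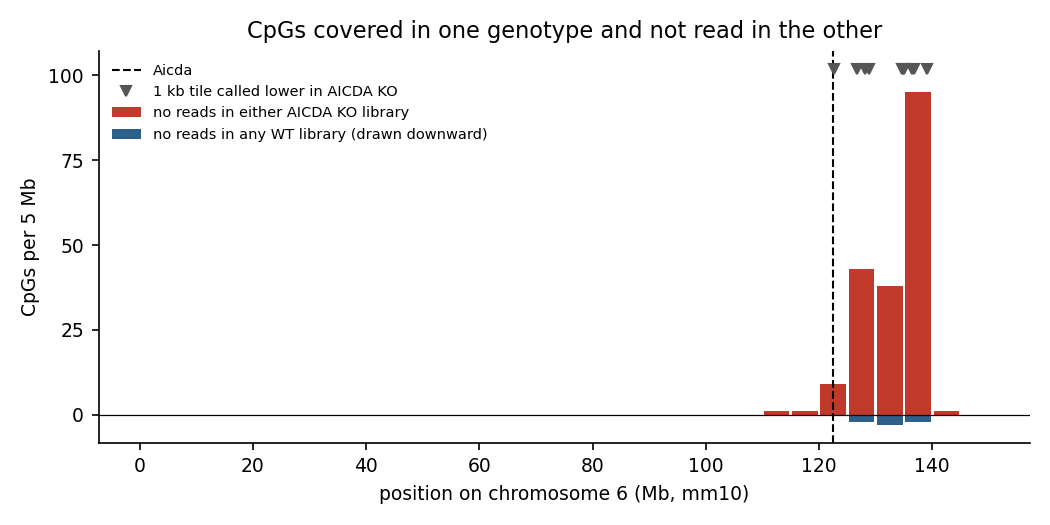
CpGs per 5 Mb of chromosome 6 (vertical axis) by position in Mb (horizontal axis); red bars count CpGs with at least 20 reads in every WT library and none in AICDA KO, blue bars, drawn downward, the reverse. Triangles mark the 10 tiles called lower in AICDA KO near Aicda, and the dashed line marks Aicda; 188 of the 197 unread CpGs lie within 20 Mb of it.

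Of 16055 gene ends, 2624 were of intermediate methylation, and both AICDA KO libraries lay above all WT libraries in 59.4% of these and below them in 1.18% (chance 10% each). Among the 13358 gene ends under 20% the shares were 11.2% and 7.76%. edgeR over all gene ends called 0 of 15736 (lowest adjusted p = 0.727; 980 at an unadjusted p under 0.05, of which 774 were higher in AICDA KO). The quasi-binomial test called 196 gene ends (193 higher), limma 0 and the binomial test 1618. edgeR over all gene ends recovered 0% of simulated changes of 15 or of 30 points, and at intermediate levels 7% and 78%. Among the 2624 gene ends of intermediate level, a set chosen after the data were seen, edgeR called 713, or 27.2%. Of these, 710 rose and 3 fell in AICDA KO, and the median difference over the 2624 was 11.8 points. The quasi-binomial test called 668 and limma 399, with 363 shared by the 3 tools. The count was 152 without AICDA KO replicate 2, 272 without replicate 3 and 433 without WT replicate 2. With the median log ratio of each library subtracted, limma called 0 (lowest adjusted p = 0.242; 307 at an unadjusted p under 0.05, 122 above and 185 below the shared shift).

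Of the called gene ends the largest rise was at Olfr417, an olfactory receptor gene. It stood at 77.8% ± 3.10 (SD, n = 2) in AICDA KO and 37.7% ± 5.23 (SD, n = 3) in WT (edgeR, adjusted p = 0.00955). Syna, which encodes the placental cell fusion protein syncytin A, was at 54.6% ± 18.2 against 18.3% ± 3.44 (adjusted p = 0.00636). Havcr2, an immune checkpoint receptor gene, was at 78.4% ± 10.01 against 43.6% ± 6.28 (adjusted p = 0.00697). H2-Eb2, of the MHC class II family, was at 80.6% ± 12.1 against 43.4% ± 17.1, and Tssk1, a testis-specific kinase gene, at 89.8% ± 4.93 against 57.7% ± 6.88. Abhd14a, Zfp951, AY358078, Hrct1 and Sppl2a completed the 10 largest, with rises of 32.2 (Sppl2a) to 38.8 points (Abhd14a). Asb18 (chromosome 1, 89951591 to 89953091) had the lowest adjusted p of the named gene ends, 0.000833, at 89.1% ± 3.07 against 57.3% ± 7.22. Ch25h, the gene of cholesterol 25-hydroxylase, fell from 34.0% ± 4.79 to 17.9% ± 3.95 (adjusted p = 0.0198), and Satb2, a chromatin organiser gene, from 30.2% ± 4.17 to 18.5% ± 0.737 (adjusted p = 0.0296). These gene ends held 3 to 9 CpGs each, with 37 reads in the lowest library of H2-Eb2 and 347 in that of Satb2. Strand was not known, so that windows named here may lie at the 3' end of their gene.

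Below 20% methylation the gene ends with the smallest p were given by value only. Wdr77 (chromosome 3, 105958498 to 105959998), a gene of an arginine methylation complex, was at 7.02% ± 0.752 (SD, n = 2) in AICDA KO and 0.0559% ± 0.0593 (SD, n = 3) in WT over 40 CpGs (edgeR, adjusted p = 0.727; quasi-binomial test, 0.000137). Tpi1, a glycolysis gene near Aicda, was at 5.89% ± 1.82 against 0.101% ± 0.175, and LOC102631992 at 2.18% ± 0.671 against 0.136% ± 0.0357. Magohb, near Aicda, stood at 2.64% ± 0.0355 against 13.5% ± 2.41 (edgeR, adjusted p = 0.727; quasi-binomial test, 0.0146). Nabp1, Marchf9, Hoxb2 and Tbc1d8 were at 0.119%, 0.0373%, 0% and 0.0462% in AICDA KO and at 2.504%, 1.88%, 1.07% and 1.59% in WT.

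Core pluripotency genes had little methylation in both genotypes. The gene end of Pou5f1 (Oct4) was at 1.48% ± 0.423 (SD, n = 2) in AICDA KO and 1.07% ± 0.974 (SD, n = 3) in WT, that of Klf4 at 0.208% ± 0.294 and 0.209% ± 0.181, and that of Sox2 at 0% and 0.983% ± 1.26. Zfp42 (Rex1) was at 8.93% ± 2.89 against 4.32% ± 0.891. At Zfp42 both AICDA KO libraries lay above all WT libraries, and at Sox2 both lay below them. Dppa3, a naive-state gene next to Aicda, was at 9.86% ± 6.26 against 17.5% ± 9.18, with overlapping libraries. The FGF genes Fgf4 (0.125% ± 0.176 against 2.16% ± 3.54) and Fgf5 (2.09% ± 0.707 against 1.53% ± 0.225) and the ERK feedback genes Spry4 and Dusp6 lay under 2.5% as group means. None of these 9 gene ends was called by edgeR, with unadjusted p-values from 0.0636 (Sox2) to 0.999 (Klf4). Nanog, Esrrb and Snrpn had too few covered CpGs. Of 28 measured pluripotency genes 27 lay under 20% and 0 were called at intermediate levels (edgeR), and of 18 primed-state genes 16 lay under 20% and 0 were called.

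Few members of the lineage lists were of intermediate level, the set in which edgeR made calls. Of all 2624 gene ends in that set 27.2% were called. Among 14 measured B-cell gene ends 5 were of intermediate level, and 2 of these were called, 3 when adjusted over the list alone. The 3 were Rag1, of the V(D)J recombinase (62.6% ± 15.6 (SD, n = 2) against 40.6% ± 6.46 (SD, n = 3)), Vpreb1, of the surrogate light chain (74.7% ± 4.85 against 52.4% ± 5.62), and, over the list alone, the kinase gene Blk (65.9% ± 3.402 against 47.9% ± 2.46). Among 88 developmental regulators 6 were intermediate, and of these Gata3 alone was called (59.6% ± 4.57 against 34.0% ± 4.85). Of 31 epithelial genes 5 were intermediate, and of these Ehf alone, an ETS factor gene, was called (72.1% ± 0.661 against 53.8% ± 5.56). Of 55 FGF and ERK genes only Klb, an FGF co-receptor gene, was intermediate, and it was called (49.4% ± 3.12 against 38.2% ± 2.40). None of 27 fibroblast genes (2 intermediate) or 27 genes of the DNA methylation machinery (1 intermediate) was called by edgeR at intermediate levels. Here too, without strand, a named window may lie at the 3' end of its gene.

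Imprinted and germline genes held most of the intermediate list members. Of 36 imprinted gene ends 16 were intermediate and 5 were called, all higher in AICDA KO. These were Sgce and Peg10, which share 1 set of CpGs (51.4% ± 5.68 (SD, n = 2) against 24.3% ± 12.04 (SD, n = 3); edgeR, adjusted p = 0.00394), Nap1l5 (50.7% ± 2.98 against 34.0% ± 10.01), H19 (47.6% ± 12.8 against 30.8% ± 5.60) and Zrsr1 (42.9% ± 9.77 against 28.4% ± 5.57). Meg3 (79.6% ± 1.71 against 70.5% ± 8.12) and Peg3 (35.2% ± 2.89 against 30.7% ± 19.09) had overlapping libraries and were not called. Of 33 germline gene ends 22 were intermediate, with a median difference of 5.91 points, and 1 was called, Sycp2 of the synaptonemal complex (83.0% ± 8.98 against 54.6% ± 12.1). The germline gene Dazl was at 46.7% ± 8.33 against 42.0% ± 4.72 and was not called. Adjusted over the list alone, the counts at intermediate levels were as given for every list but the B-cell one. In the fit over all gene ends edgeR called 0 members of each list, both adjusted over all gene ends and adjusted over the list alone, with 0 to 6 members per list at an unadjusted p under 0.05. limma called 0, and the quasi-binomial test called only Sgce and Peg10. Leaving out 1 library ended calls of named gene ends. Of 24 called, 16 were lost without AICDA KO replicate 2, 12 without replicate 3, and 5, 7 and 5 without WT replicates 1, 2 and 3. Asb18, Abhd14a, Sppl2a, Sgce and Peg10 passed in all 5 of these fits. Without AICDA KO replicate 2 the difference was 13.2 points at Zfp951 (36.9 with all libraries), 23.5 at Syna (36.4), 7.74 at H19 (16.8), 7.62 at Zrsr1 (14.5) and 33.1 at Rag1 (22.0). Without replicate 3 it was 10.99 points at Rag1, 60.6 at Zfp951 and 25.9 at H19. Other differences of called gene ends stayed within 1.5 times their value.

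**Figure D5:**
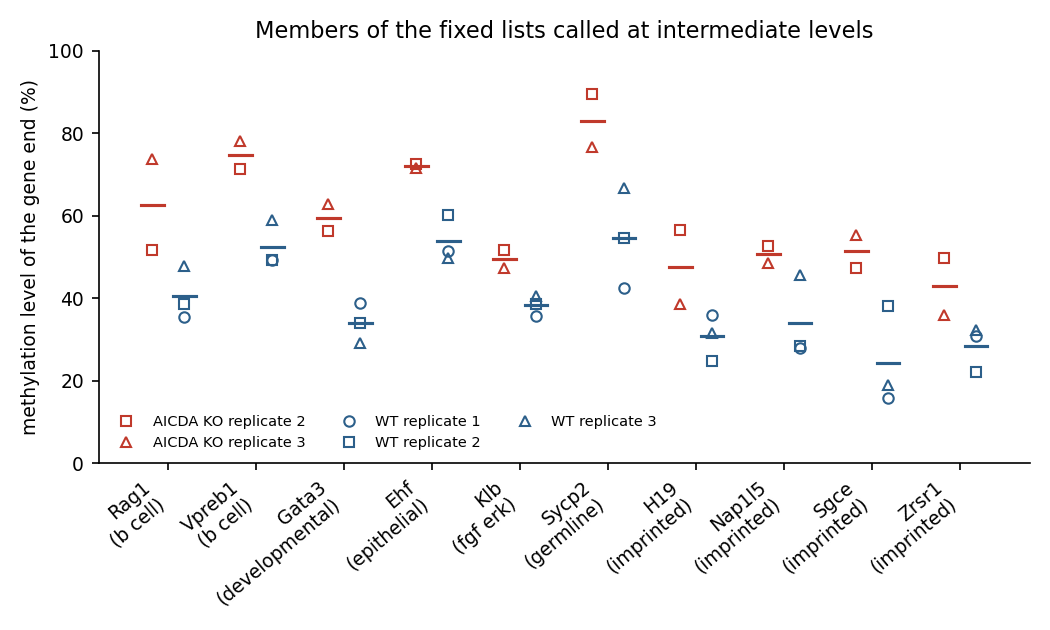
Methylation level in percent (vertical axis) of the gene ends called at intermediate levels among the fixed lists (horizontal axis, list in brackets); red symbols are AICDA KO, blue symbols WT, symbol shape gives the replicate and bars the group means. Rag1 has means of 62.6% and 40.6%, and Peg10, with the same CpGs as Sgce, is not drawn.

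As whole sets, none of the 10 lists passed camera, which compares a list with the other gene ends. The lowest adjusted p by camera was 0.0799, for the developmental regulators in the downward direction (adjusted p = 0.362 with an estimated correlation), where the median difference was -0.182 points and the mean difference 0.256 points. fry, which tests whether the members of a list move 1 way on balance, gave adjusted p-values of 0.168 or more, and under other processing passed only for the B-cell list, in 3 settings. Its test for change in either direction passed for developmental regulators (adjusted p = 0.00296), B-cell genes (0.0235), germline genes (0.0235), epithelial genes (0.0277) and imprinted genes (0.0277). That test does not compare a list with other gene ends, so that a shift shared by intermediate gene ends can pass it. The lists that passed held 5 (B cell and epithelial) to 22 (germline) intermediate members, and the others 1 or 2. camera's direction was downward for the germline, epithelial and pluripotency lists, whose median differences were 1.67, 0.0855 and 0.0514 points.

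Single CpGs gave few calls. The moderated quasi-binomial test called 95 of 698221 autosomal CpGs, 82 higher and 13 lower in AICDA KO (lowest adjusted p = 0.000102), while 125903 had an unadjusted p under 0.05, 122812 of them higher. limma called 0 and the binomial test without overdispersion 183561. With coverage of at least 20 the count was 3290, and with a coverage maximum 9 were called, all 9 lower in AICDA KO. Thinning to equal coverage left 0 calls. The count was 0 without either AICDA KO library, and 21445, 24958 and 18828 without WT replicates 1, 2 and 3.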

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

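The tests of DNA copies around Aicda and of CpG density were set before their results were seen, and all other tests in this part were chosen only after.

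AICDA KO libraries lacked reads at 197 of the 733449 autosomal CpGs that had at least 20 reads in every WT library. These sites take no part in the comparisons, which need coverage in all libraries, and so are a signal outside the main measurement. 188 of them lay within 20 Mb of Aicda on chromosome 6, from position 114506764 to 140166310, a window with 1.52% of the covered CpGs. In the reverse direction 7 of 649840 CpGs lacked reads in WT, all 7 in this window. Lower depth of the AICDA KO libraries would spread unread CpGs over all chromosomes, which the share of 95.4% near Aicda argues against. The median coverage ratio of AICDA KO to WT there was 0.985 of that elsewhere, which argues against loss of DNA copies over most of the window. This ratio used only CpGs with at least 10 reads in every library. It therefore cannot weigh loss of DNA at the unread CpGs themselves. Sequence variants linked to the knocked-out gene, such as DNA of another mouse strain left by crossing, are a candidate explanation. CpGs at 2% or less in every WT library and at 40% or more in both AICDA KO libraries numbered 0 in this window and 9 elsewhere. In the other direction, 16 CpGs were at 2% or less in both AICDA KO libraries and at 40% or more in every WT library. Of the 16, 15 lay in this window. Of the 10 lowered tiles there, 3 (Tspan9, Clec2g and Ddx47) held such all-or-none CpGs, and summed over their other CpGs they differed by under 10 points in 2 of the 3 and were higher in AICDA KO by 4.84, 11.8 and 6.51 points. Over CpGs whose methylated reads in AICDA KO a lost CpG would not leave, the fall stayed in the 4 tiles without a sign of a variant (Aicda, 18.6 points, Kcna1, 11.2, Mansc1, 22.7, and Wbp11, 13.7) and in 2 of 2 with a CpG at 2% or less (Dusp16, 29.2 at 1 CpG, and Gm36897, 14.5), against lost CpGs as the whole cause in these 6, while Rergl, near an unread CpG, kept 0 falls and fits it. The strains are not given in the sources used here, and an effect of nearby variants on methylation and a biological effect of the genotype on these 6 tiles stay open and untested.

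The higher methylation of both AICDA KO libraries was weighed against technical explanations. Unconverted cytosines would have needed 29.1% of unmethylated reads to be misread. This would put CpGs under 20% at 30.5%, where AICDA KO stood at 2.25%. Thinning to equal coverage left 6.40 points. Random removal of reads leaves the expected level of a CpG unchanged, so that thinning cannot weigh a difference in depth. DNA of methylated cells with an intact Aicda gene, at a share of 29.1%, would have kept more reads at the segment of lost coverage. That segment of Aicda kept 5.08% of WT reads, scaled by the reads of the other segments of the gene. This argues only against DNA that reads as WT does at the segment. Fewer X chromosomes, known to go with higher methylation in pluripotent mouse cells, are argued against in AICDA KO replicate 2 by its X coverage of 1.07, and cannot be told apart from genotype in replicate 3, at 0.75. The 10 splits of the 5 libraries are too few for a share under 0.05, with 24077 intermediate tiles for the real split, the 1 split that reached this number, and at most 1 for the others. Both AICDA KO libraries also listed more cytosines than any WT library, at a lower median coverage. Whether this bears on the levels was not tested. Library batch, clonal history and loss of AICDA stay open, the last as a hypothesis.

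The smaller shift at CpG-dense sites was weighed against level and coverage. Among CpGs with a mean level of 50 to 70% the shift at 25 to 29 CpGs within 250 bp was 0.554 of that at fewer than 5 (10.9 against 19.6 points), which argues against a different starting level as the whole cause. After thinning, the ratio at intermediate levels was 0.336. Thinning evens coverage between libraries at each CpG, not between dense and sparse sites, so that it cannot weigh higher coverage at dense sites. Over all autosomal CpGs the median coverage by library was 26 to 39 at over 25 CpGs within 250 bp. It was 27 to 44 at under 10, so that dense sites were not covered more. The trend ended at 40 or more CpGs, with 20.2 points in the same level band over 144 CpGs. A genotype effect that depends on CpG density stays a hypothesis, and was not tested otherwise.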

How the results depend on the processing

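The replicate block, the tests and the settings named here were planned, except the fits at intermediate levels, the whole gene span and the centring over intermediate regions, which were chosen after the data were seen. The global difference stayed between 6.19 and 6.81 points under 12 alternatives, and that of the X chromosome between 7.01 and 7.43 under 10. 9 to 10 of 10 classes had both AICDA KO libraries above all WT libraries. Without 1 library each, the ranges were 6.19 to 6.51 points, 7.01 to 7.43 points and 9 to 10 classes, 0 lists by camera, 0 tiles and 0 to 1 gene ends over all regions, 6560 to 19187 intermediate tiles, 152 to 545 intermediate gene ends and 0 to 24958 CpGs. 1 list passed camera, the developmental regulators, with coverage of at least 20, separate strands or thinning, each at the preset correlation (at an estimated correlation the main fit gave an adjusted p of 0.362). The B-cell list passed fry (adjusted p = 0.168 in the main fit) when median centred (0.00336), with separate strands (0.0242) and with thinning (0.0386). Over all gene ends the quasi-binomial test called 196, the binomial test 1618 and edgeR over whole gene spans 1. Over all tiles the quasi-binomial test called 18115 and the binomial test 48101.

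At intermediate gene ends (713) the counts were 462 with coverage of at least 20, 399 with limma, 0 with limma on centred log ratios, 1558 with the binomial test, 118 at 25 points or more, 406 with at least 5 CpGs and 5038 for whole gene spans. At intermediate tiles (24077) they were 15692 with coverage of at least 20, 45795 with the binomial test, 4746 at 25 points or more, 10031 with at least 5 CpGs and 0 with limma on centred log ratios. Stricter coverage and CpG minimums left fewer regions to test, a higher difference threshold removes calls by construction, and centring removes a shift shared by all regions; otherwise the cause was not tested. The CpG count (95) was 3290 with coverage of at least 20, 9 with a coverage maximum (0 higher and 9 lower, where the main fit had 82 and 13), 56 with separate strands, 320 with X and Y, 0 with thinning, 0 with limma and 183561 with the binomial test, and the cause was not tested. The replicate block gave 271 intermediate gene ends, 22001 intermediate tiles and 0 CpGs, gene ends, tiles and lists elsewhere. Deviations of same-numbered libraries from their group means correlated at 0.00177 and 0.00326 over intermediate tiles. A correlation over tiles cannot show an offset shared by all tiles, and the labels do not say what a shared number stands for. Whether same-numbered libraries are paired thus stays open. No called class, list or named gene end reversed, while the called CpGs turned from mostly higher to all lower with a coverage maximum. Counted once per setting, 120 values of classes, 147 of lists and 794 of named gene ends stayed on the same side of the threshold. 3 values of lists, all of the developmental regulators, and 3 of gene ends gained a call, and 115 of gene ends lost one. With 200 regions or CpGs changed and the rest unchanged, no simulated change of 15 or 30 points was recovered at single CpGs. Nor was any over all tiles or all gene ends. A shift shared by many regions differs from this setting. The quasi-binomial test recovered 0% there and yet called 18115 real tiles. What share of this limit depth accounts for was not tested.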

Other observations

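The tests of the imprinted and germline medians were set before their results were seen, and the tests of the developmental regulators, of single libraries and of the number of calls were chosen only after.

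Germline genes, many of them silenced by promoter methylation outside the germ line, had a smaller median difference than gene ends of similar level, in 1 of the 2 AICDA KO libraries. Their 33 measured gene ends had a median difference of 1.67 points between AICDA KO and WT. 10000 random lists of gene ends matched on mean level and CpG number had a median of 5.65 points, with 95% of them between 2.67 and 8.74. The germline median lay at percentile 0.31 of them (2-sided p against the random lists = 0.0062, Benjamini-Hochberg adjusted over 10 lists 0.031). Taken alone against WT, AICDA KO replicate 2 had a germline median of 4.76 points (6.09 in matched lists, percentile 17.2) and replicate 3 one of -1.18 points (4.74, percentile 0). The shortfall thus rested on replicate 3, and the range set beforehand was too narrow a bound, since it left out the spread between libraries. camera gave an adjusted p of 0.632, and 0.837 at the estimated correlation between germline gene ends of 0.222. Whether these gene ends merely follow the shift of similar gene ends cannot be told apart from a change of their own with 2 such libraries. Over the 22 intermediate members the median was 5.91 points, against 10.1 in matched lists. Of these 22, 1 was called, where 95% of matched lists had 3 to 10 calls, a count that rests on the same libraries. Genes are not independent replicates, and the spread between lists says nothing of other clones. Germline levels in AICDA KO also varied by library, with a list mean of 38.2% ± 4.25 (SD, n = 2) against 35.1% ± 0.354 (SD, n = 3) in WT.

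Imprinted gene ends as a list did not stand apart from matched lists. Their median difference of 1.497 points lay at percentile 86.5 of matched lists (95% of them within 0.0759 to 2.26 points), and that of the 16 intermediate members, 9.04 points, at percentile 60.4. Taken alone, AICDA KO replicates 2 and 3 lay at percentiles 92.1 and 82.1, while WT replicate 3, against the other WT libraries, lay at percentile 0.55 with a median of -0.822 points. Counting shared windows once, 4 of 14 intermediate imprinted gene ends were called, where 95% of matched lists had 1 to 6 calls. The list median and the number of calls are consistent with the hypothesis that the list moved like gene ends of the same level and CpG number, while the single called genes were not tested.

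Developmental regulators, mostly CpG-rich genes kept unmethylated in pluripotent cells, had a median difference of -0.182 points over 88 gene ends. This lay at percentile 0.04 of matched lists, 95% of them within -0.0607 to 0.245 points (2-sided p against the random lists = 0.0008, adjusted p = 0.008). camera did not call the list (adjusted p = 0.0799, and 0.362 at an estimated correlation), and its mean difference was 0.256 points. The p against random lists draws genes and not libraries. Genes, here several of the Hox clusters, are not independent replicates, and the spread between lists says nothing of other clones. Taken alone, AICDA KO replicate 2 lay at percentile 0 of matched lists and replicate 3 at percentile 30.5, so that the low median rested on replicate 2. Of the 88, 14 lay below all WT libraries in both AICDA KO libraries and 8 above. Among all gene ends under 20%, which hold 82 of the 88, 7.76% lay below and 11.2% above. Neurog2, for which both AICDA KO libraries had 0% over 8 CpGs, was at 1.90% ± 0.487 (SD, n = 3) in WT, and Hoxd1 was at 0.870% ± 0.679 (SD, n = 2) against 2.05% ± 0.205 (SD, n = 3). These 2 genes were chosen after their values were seen.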
